A study of Homo sapiens with 2 samples.

How the data were processed

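Single cells of cortical organoids grown from H9 human embryonic stem cells were measured by droplet-based 3′ RNA sequencing, with 1 WT library and 1 library of cells with a homozygous CRISPR deletion of SPAST exon 17. The groups come from the sample titles. Per the labels' protocols, organoids were dissociated with Accutase, and about 20000 cells per library were targeted at a minimum mean depth of 50000 reads per cell. The labels disagree on the chemistry and sequencer: the series design names a Chromium 3′ v3.1 kit and a NovaSeq 6000, and the sample protocols a GEM-X v4 kit and a NovaSeq X Plus. Which was used was not settled here.

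The deposited values are whole-number UMI counts per gene and barcode that the authors made with Cell Ranger 9.0.0, per the file headers and the submitters' processing notes. Per the same notes the genome build was GRCh38, and R 4.2.2 and Seurat 4.2.2 were also used; their role is not given in the sources used here, nor is the annotation release. Each library held exactly 20000 barcodes and 38606 genes, with 129 barcodes found in both. Gene positions came from GENCODE 44 on GRCh38, in which 24 feature IDs had no match. The labels do not say whether counting used strand, so values of antisense genes such as DLX6-AS1 and FEZF1-AS1 are uncertain, as are those of genes that share reads with a paralog or overlap another gene, such as MT-ND4L and MT-ATP8.

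Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes, which 17662 WT and 13773 SPG4 barcodes met. Scrublet, run through scanpy 1.11.5 at an expected rate of 0.08, marked under 0.5% of cells at its own threshold, so the top 8% by score, ties included, were removed, 1464 WT and 1166 SPG4 cells. The kept cells held 85.5% of the WT and 86.8% of the SPG4 UMIs. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken, and 30 principal components, 15 neighbours and Leiden resolution 1 gave 31 clusters without integration of the libraries. SPAST, XIST, Y-linked, mitochondrial and ribosomal protein genes were left out of the variable genes. Clusters were named from 20 fixed marker lists with at least 3 detected markers; 23 clusters were named and 8 were not. The scoring rule for names and the merging of outer radial glia with radial glia were set after the data were seen, so shares may differ from those of other annotations.

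Raw UMIs were summed per library and class and divided by the class total. Classes with at least 200 cells in both libraries were compared: GABAergic neuron-like, radial glia-like and cycling progenitor-like cells. Log2 ratios of SPG4 over WT used a pseudocount of 1 CPM, and folds used none. Levels carry exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95%. A gene with 0 UMIs was set to 3 UMIs over the group to give a bound, and the limit given in the report for a class with 0 cells is likewise 3 cells over the cells kept, not the upper bound of the exact interval (0.0228% for WT). The exact interval of such a gene's ratio reaches below its bound. For NEUROD6 over all cells it reaches 50113-fold, against a bound of 61621-fold. With 1 library per group no p-value, standard error or count of changed genes was made. Medians of 29 function lists were taken over members with at least 10 CPM in either library, with intervals from 200 resamples of the counts and a percentile among 10000 random lists of the same size matched on expression in 20 bins. Members at least 1.5-fold apart were counted as higher or lower. A list median is reported if it lay outside the central 95% of random lists with a size of at least 0.25 in a class or 0.4 over all cells, a rule set after the medians were seen; 7 lists tied to spastin function are always given, which makes 56 medians.

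The filters, the main tests, the marker and function lists and the rule for named genes were fixed before the data were examined. That rule takes the 12 genes with the highest and the 12 with the lowest log2 ratio in radial glia-like cells, and the 4 highest and 4 lowest in the other classes, among genes with at least 50 CPM in either library and without clone-like symbols. It adds the 4 members of each list with the largest ratios, and the markers of classes whose shares are compared. The same 4 and 4 were taken over all cells. A few genes that the rule names are not reported here. The rule also named the glutamatergic class, which could not be compared since WT held none. Shares of cells by markers alone, the chromosome 1 region and the genes around PEG3 were chosen after their values were seen. The region was found by a search along the autosomes for the stretch of genes with the highest summed score on each chromosome. A gene's score was its log2 ratio, limited to a size of 1 and averaged over the 3 classes, minus 0.3. The same was done for lower ratios. Runs of at least 20 genes were kept, and single genes in them could lie below 0.3.

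The steps were tested on simulated counts with 200 genes changed by known folds. In GABAergic neuron-like cells (4433 genes) the median recovered fold was 1.49 at 1.5-fold (71 genes), 1.98 at 2-fold (66 genes) and 3.98 at 4-fold (63 genes). In radial glia-like cells (4727 genes) it was 1.50 (67 genes), 2.01 (73 genes) and 4.01 (60 genes), and in cycling progenitor-like cells (4481 genes) 1.48 (52 genes), 1.96 (69 genes) and 3.99 (79 genes). The intervals of unchanged genes held the true ratio in 95.5%, 95.0% and 94.8% of cases. Of 100 simulated lists of 20 unchanged genes, 4, 6 and 1 lay outside the central 95% in the 3 classes, and 100 of 100 did so at 1.5-fold. The simulated counts held counting error only, and the lists were drawn from the same genes as the random lists. These rates for lists therefore check the calculation, and they cannot give error or detection rates for the real lists. The search for runs found 0 runs in 100 shuffles of 9094 genes, and it found an implanted run of 100 genes at 1.5-fold in 100 of 100. Shuffling removes any likeness between neighbouring genes, so these counts give no rate of false runs on real chromosomes.

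The alternatives covered the cell filter, doublets, clustering, normalization, the weight of cells, thinning to 3000 UMIs, the minimum CPM and the pseudocount, and 3 kinds were added after the data were seen: weighting WT clusters as in SPG4, leaving out clusters of low UMI counts, and leaving out genes of distal chromosome 1q. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.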

Results

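Single-cell RNA sequencing compared cortical organoids of 2 genotypes, both derived from H9, an established human embryonic stem cell line. One genotype was wild type (WT), and the other carried a homozygous CRISPR deletion of exon 17 of SPAST and was labelled SPG4, the name of the hereditary spastic paraplegia that follows from SPAST mutation. SPAST encodes spastin, an enzyme that severs microtubules. Organoids were cultured for up to 100 days, and each genotype was represented by 1 library. No difference below therefore has a replicate check, and no test was made. The WT library held 272811011 unique molecular identifiers (UMIs) in 20000 barcodes, and the SPG4 library 293739125 in 20000 barcodes. After filtering and doublet removal, 16198 WT cells with a median of 12942.5 UMIs and 4509 genes were kept, and 12607 SPG4 cells with a median of 19846 UMIs and 5871 genes. Barcodes under 1000 UMIs made up 11.5% of the WT library and 30.6% of the SPG4 library. Levels are UMIs of a gene per 1000000 UMIs of the summed cells (CPM), and every interval given is a 95% interval that covers counting error only.

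SPAST was measured in both libraries and was lower in SPG4 over all cells, in GABAergic neuron-like cells and in cycling progenitor-like cells, while radial glia-like cells of the 2 libraries held similar levels. Over all kept cells it stood at 152.1 CPM (150.5 to 153.7) in WT and 116.0 CPM (114.6 to 117.3) in SPG4, a ratio of 0.762 (0.751 to 0.774). In GABAergic neuron-like cells the levels were 176.0 and 125.7 CPM, a ratio of 0.714 (0.680 to 0.750), and in cycling progenitor-like cells 106.3 and 70.6 CPM, a ratio of 0.664 (0.607 to 0.725). In radial glia-like cells they were 66.4 and 66.0 CPM, with a ratio of 0.995 (0.918 to 1.08). That class mixed clusters of different level, with 66.3 and 76.4 CPM in clusters 23 and 27 of WT and 59.8 and 108.2 CPM in clusters 17 and 26 of SPG4. Its log2 ratio was 0.12 with the mean of per-cell CPM and -0.15 without clusters of low UMI counts, an alternative chosen after the data were seen. SPG4 glutamatergic neuron-like cells, which had no WT counterpart, held 126.1 CPM (124.4 to 127.8). SPAST (ENSG00000021574) lies on chromosome 2 at 32063556 to 32157637 of GRCh38, on the plus strand. Exon 17 is the last exon of transcript ENST00000315285 and spans 32154374 to 32157637, with 120 bp of coding sequence up to 32154493 and the stop codon and 3′ untranslated region after it. The labels do not give the ends of the deletion, and a count per gene does not record where in the gene a read fell, so the SPAST count checks neither the edit nor the labels.

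**Figure D1:**
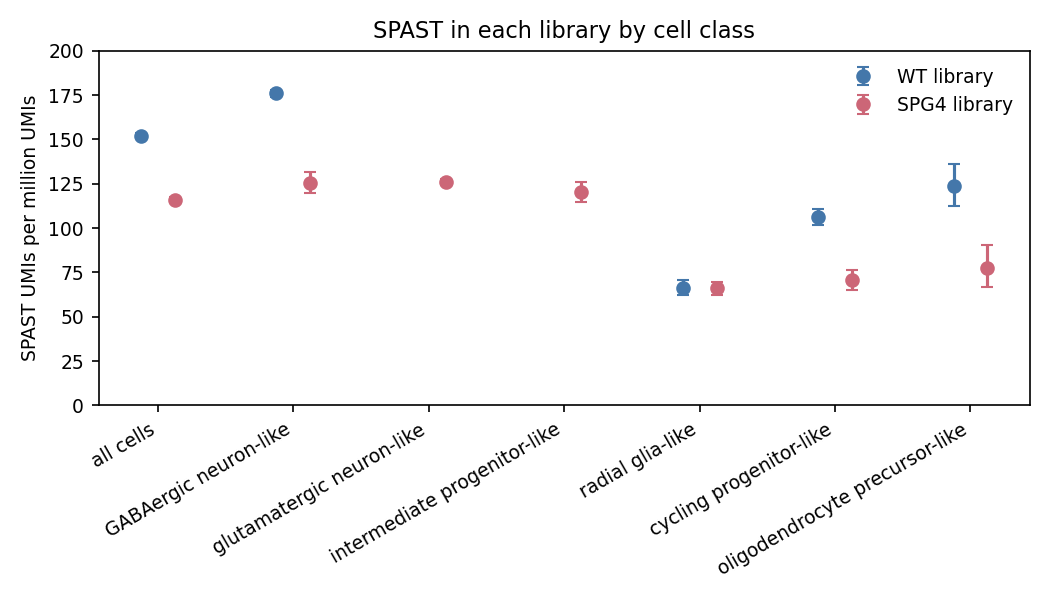
SPAST level in CPM (vertical axis) in all kept cells and in 6 cell classes (horizontal axis), with 1 point per library and bars for the 95% counting interval. WT points lie above SPG4 points in all cells, where they stand at 152.1 and 116.0, and the points of radial glia-like cells lie at 66.4 and 66.0.

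The first question the design raises is which cells each organoid library held, and the libraries differed most in their neurons. GABAergic neuron-like cells, inhibitory neurons named from DLX and GAD genes, made up 69.9% of WT cells (69.2 to 70.6) and 5.95% of SPG4 cells (5.54 to 6.38). Glutamatergic neuron-like cells, excitatory neurons of the cortical lineage, made up 53.2% of SPG4 cells (52.3 to 54.1), while 0 of 16198 WT cells fell in that class, which allows a share of up to 0.0185%. Intermediate progenitor-like cells, which give rise to glutamatergic neurons, numbered 925 in SPG4 (7.34%) and 5 in WT (0.0309%). Radial glia-like cells, neural stem cells by their markers, made up 4.95% of WT and 9.55% of SPG4 cells. Cycling progenitor-like cells made up 4.70% and 3.25%, and oligodendrocyte precursor-like cells 1.80% and 0.896%, but the order of both was reversed in some clusterings. Cycling cells made up 1.65% of WT and 3.01% of SPG4 at Leiden resolution 0.5, and 2.69% and 3.43% with genes centred within each library. Oligodendrocyte precursor-like cells made up 0.364% and 0.603% with centred genes, and with each library clustered on its own this name went to 1.12% of WT and 0 SPG4 cells, but the name astrocyte-like to 0 WT and 1.41% of SPG4 cells, so the names there do not compare the same cells. In the main clustering the oligodendrocyte precursor-like class was cluster 25 alone. That cluster scored higher for the cycling progenitor markers (4.22) than for those of oligodendrocyte precursors (3.32). A cortical hem-like cluster of 73 cells, named from WNT and RSPO genes of the dorsal midline, came from SPG4 alone (0.579%). Clusters left unnamed held 18.6% of WT and 19.2% of SPG4 cells, but the near-equal shares depended on the processing: over the filters and clusterings tried the WT share was up to 31.3%, and the SPG4 share lay between 6.40% and 25.9%. Among them, clusters 14 and 18 carried GABAergic markers and held 5.52% and 4.43% of WT cells but 0.032% and 0.246% of SPG4 cells. Cluster 19 carried glutamatergic markers at low UMI counts and held 5.44% of SPG4 cells and 0 WT cells, cluster 24 carried radial glia markers and held 2.46% of WT and 0.23% of SPG4 cells, and cluster 7, of low UMI counts, held 0.772% and 9.08%. A choroid plexus-like class was named under other settings, with 0.685% of WT and 8.38% of SPG4 cells when called doublets were kept and 0.317% and 1.20% with the looser filter, and whether these are the cells of cluster 7 was not tested. TTR, a marker of choroid plexus, was 635-fold higher (411 to 1040) in SPG4 over all cells. The other markers of its list did not follow to that extent. CA12 was 2.61-fold higher, KCNJ13 stood at 1.55 and 1.63 CPM, and OTX2 was 3.53-fold lower. CLIC6, FOLR1 and AQP1 stood under 1 CPM in both libraries. With called doublets kept, the choroid plexus-like cells had low UMI counts, with medians of 2088 in WT and 2209.5 in SPG4. Most clusters came almost wholly from 1 library, and with 1 library per genotype such a cluster may stand for that library and not for a cell type. With genes centred within each library before clustering, the SPG4 share of GABAergic neuron-like cells was 0.278% and the WT share of glutamatergic neuron-like cells 1.25%.

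**Figure D2:**
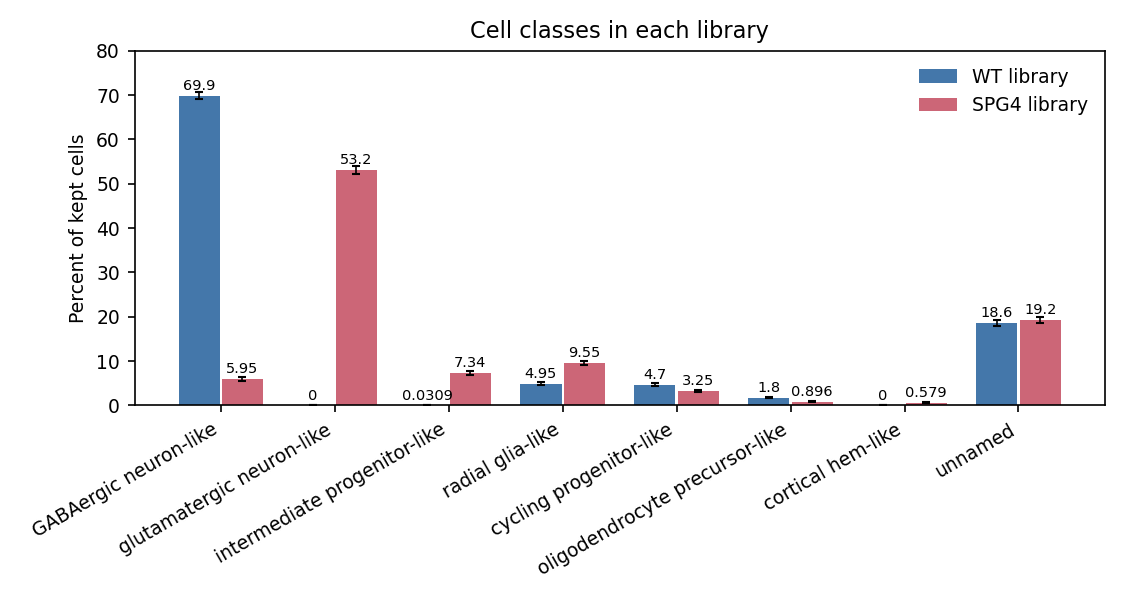
Share of kept cells in percent (vertical axis) per cell class (horizontal axis), with 1 bar per library and the exact binomial 95% interval as the error bar. GABAergic neuron-like cells make up 69.9% of the WT library and 5.95% of the SPG4 library, and glutamatergic neuron-like cells 0% and 53.2%.

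The marker genes behind these names differed between the libraries without reference to clusters. NEUROD6, a transcription factor of cortical excitatory neurons, had 0 UMIs over all WT cells and 792.2 CPM in SPG4, at least 61621-fold higher when WT is set to 3 UMIs. NEUROD2, of the same family, stood at 0.356 CPM in WT and 405.5 CPM in SPG4, and SLA and PRDM8 were 404-fold (355 to 461) and 619-fold (462 to 849) higher in SPG4. FEZF2, a regulator of deep-layer neurons, stood at 1.12 and 49.3 CPM. TBR1, of the same neurons, was 84.8-fold higher, and the vesicular glutamate transporter SLC17A7 93.9-fold. Not every marker of these neurons was higher: UNC5D, a netrin receptor, stood at 249.3 CPM in WT and 59.2 CPM in SPG4, 4.21-fold lower. EOMES and NEUROG2, regulators of intermediate progenitors, were 101-fold and 494-fold higher in SPG4, while HES6 and PENK, of the same marker list, stood at 50.1 and 51.6 CPM and at 4.50 and 4.72 CPM. BCL11B, which is expressed by deep-layer excitatory and by striatal inhibitory neurons, stood at 499.3 CPM in WT and 547.4 CPM in SPG4. In the other direction DLX1, DLX2 and DLX5, transcription factors of ventral forebrain neurons, were 14.4-fold, 17.1-fold and 17.4-fold lower in SPG4. The GABA synthesis enzymes GAD1 and GAD2 were 9.26-fold and 15.4-fold lower, and the vesicular GABA transporter SLC32A1 10.3-fold lower. ERBB4, a neuregulin receptor of interneurons, stood at 4048 CPM in WT and 167.0 CPM in SPG4, SP9, a transcription factor, at 72.5 and 3.25 CPM, and DLX6-AS1 at 2152 and 107.9 CPM. PEG3, an imprinted zinc finger gene, had 80.4 CPM in WT and 2 UMIs over all SPG4 cells, 10249-fold lower (2837 to 84638). Cells were also counted by markers alone, a count defined after the data were seen. With each cell thinned to 3000 UMIs, 56.7% of 11268 SPG4 cells held at least 2 of 5 glutamatergic markers and fewer than 2 of 6 GABAergic markers, against 0 of 14862 WT cells; the reverse held in 6.88% of SPG4 and 83.7% of WT cells. Without thinning the glutamatergic shares were 68.3% and 0.0185%.

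Over all cells, the median levels of the cell division and forebrain patterning lists were lower in SPG4, and those of cholesterol synthesis, synapses and axon growth were higher. Of 24 genes of the G2 and M phases, 22 were at least 1.5-fold lower in SPG4, with a median log2 ratio of -1.07 (-1.09 to -1.05). UBE2C stood at 94.6 CPM in WT and 28.4 CPM in SPG4, MKI67 at 120.2 and 42.3 CPM, and TOP2A at 188.3 and 71.7 CPM. Of 18 measured S phase genes, 11 were lower (median -0.69), among them PCNA at 55.5 and 28.1 CPM. After thinning each cell to 3000 UMIs, 12.3% of WT cells (11.8 to 12.9) and 10.3% of SPG4 cells (9.70 to 10.8) held at least 3 UMIs of the G2 and M list; 1336 WT and 1339 SPG4 cells were too shallow to enter. Without thinning the shares were 42.5% and 59.4%, in the opposite order. Forebrain patterning factors had a median of -0.89, with 9 of 17 lower and 6 higher: SIX3 stood at 22.3 CPM in WT and 0.451 CPM in SPG4, while EMX1, a factor of the dorsal cortex, stood at 0.0557 and 22.5 CPM and LMO3 at 57.4 and 683.0 CPM. Cholesterol synthesis genes had a median of 0.72, with 17 of 22 higher and 0 lower, among them HMGCS1 at 69.8 and 199.1 CPM and INSIG1 at 20.6 and 58.2 CPM. Axon growth genes had a median of 0.46 (14 of 30 higher, 3 lower; PLXNA4 67.1 and 459.4 CPM, DCC 135.4 and 630.3 CPM, but UNC5C 171.3 and 27.5 CPM). Synapse genes had a median of 0.43 (11 of 32 higher, 2 lower), with NLGN1 at 307.6 and 1100 CPM and NRXN3 at 6144 and 585.8 CPM. Mitochondrially encoded transcripts had a median of 0.46, though only 1 of 13, MT-ND5, was more than 1.5-fold higher. The interferon response list had a median of -0.47, with 2 of 6 measured genes at least 1.5-fold lower (HLA-B 23.3 and 11.1 CPM), and the reactive astrocyte list one of -0.54, with 1 of 5 lower (S100A10 21.9 and 4.38 CPM). The reactive astrocyte median became 0.01 with no minimum CPM. These values mix the shares of the classes with expression inside them. In addition, 21 genes specific to glutamatergic neuron-like cells stood at a median of 6.31%, 3.16% and 3.74% of their level there in SPG4 GABAergic, radial glia-like and cycling cells; the source of these UMIs was not tested.

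Within radial glia-like cells (802 WT and 1204 SPG4), the genes with the largest differences included regulators of progenitor identity in both directions. The forebrain patterning list as a whole had a median log2 ratio of 0.16, with 8 of 19 genes higher and 5 lower in SPG4, at percentile 92.1 of random lists. TFAP2C, a transcription factor of cortical progenitors, stood at 1.17 CPM in WT and 58.3 CPM in SPG4, 49.7-fold higher (31.7 to 82.9), and LEF1, an effector of WNT signalling, at 2.72 and 85.8 CPM, 31.6-fold higher (23.4 to 43.6). HMGA2, a chromatin protein of young neural stem cells, was 9.17-fold higher (8.02 to 10.5). Among membrane and adhesion proteins, TMEM132D was 31.7-fold, the cadherins CDH12 and CDH23 15.4-fold and 10.7-fold, the ephrin receptor EPHA6 10.6-fold, the connexin GJC1 9.16-fold and the potassium channel KCNQ3 8.29-fold higher in SPG4. DCT, LYPD1 and PHLDA1 were 14.3-fold, 7.35-fold and 6.64-fold higher. On the other side PEG3, a paternally expressed zinc finger gene, stood at 70.7 CPM in WT and had 0 UMIs in SPG4, at least 484-fold lower against 3 UMIs. CRH, the corticotropin-releasing hormone, was 188-fold lower (95.0 to 436), and GSX2, a transcription factor of the ventral forebrain, 35.3-fold lower (26.0 to 49.0). GJA1 and SPARCL1, both abundant in astrocytes, were 49.9-fold (35.0 to 73.8) and 37.6-fold (29.3 to 49.0) lower, and NTRK2, the receptor of brain-derived neurotrophic factor, stood at 538.2 and 29.8 CPM. RGS6, a regulator of G protein signalling, stood at 1658 and 48.3 CPM, and LHFPL3 at 182.1 and 6.29 CPM. SPON1, NPNT and ANOS1, which encode secreted or matrix proteins, were 30.5-fold, 21.3-fold and 19.5-fold lower. The extracellular matrix list did not go one way, with 3 of 15 higher, 5 lower and a median of -0.25 at percentile 4.39; COL4A2 was 9.14-fold and COL4A1 7.29-fold higher. FEZF1-AS1 was 26.0-fold lower. Fixed markers of other regions and types differed as well: DLX1 stood at 149.3 CPM in WT and 11.8 CPM in SPG4, the outer radial glia marker HOPX at 511.1 and 70.2 CPM, the astrocyte marker AQP4 at 50.5 and 2.14 CPM, and EMX1 at 0 and 23.3 CPM. Clusters 23 and 27 held 56.2% and 38.0% of the WT cells of this class, while clusters 17 and 26 held 67.4% and 29.1% of the SPG4 cells, so the values compare different clusters under 1 name. Clusters 23, 27 and 26 were named from the outer radial glia markers, HOPX among them, and cluster 17 from the radial glia markers. HOPX and CRH were among the 10 leading genes of cluster 23. Their ratios were not separated from this difference in naming.

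Several gene groups differed within radial glia-like cells. Mitochondrially encoded transcripts were lower in SPG4, with a median log2 ratio of -0.70 (-0.73 to -0.66), 10 of 13 genes lower and 0 higher: MT-ND3 stood at 191.4 and 79.5 CPM and MT-CO3 at 1161 and 561.5 CPM. Over all kept cells, mitochondrial UMIs made up a median of 0.325% per cell in WT and 0.434% in SPG4. The medians were 0.41% and 0.125% in clusters 23 and 27, mostly of WT cells. They were 0.167% and 0.08% in clusters 17 and 26, mostly of SPG4 cells. The lower list median was not separated from this difference between clusters. Interferon response genes had a median of -0.66 (-0.74 to -0.58), with 8 of 14 lower and 2 higher; IFIT2 stood at 20.9 and 5.26 CPM and IFIT3 at 28.7 and 7.41 CPM, but IFI44L at 22.7 and 59.9 CPM. With no minimum CPM that median was -0.31. Axon growth genes had a median of -0.66 (13 of 25 lower, 8 higher), with the guidance cue NTN1 at 60.3 and 4.44 CPM, ANK2 at 2050.5 and 589.7 CPM and EPHB1 at 75.4 and 19.1 CPM, against EPHA4 at 36.1 and 121.6 CPM. The reactive astrocyte median was -0.59 (4 of 8 lower, 2 higher; CD44 33.8 and 6.39 CPM, CRYAB 85.5 and 271.9 CPM), and that of ion channels -0.56 (4 of 14 lower, 2 higher; KCNH7 1632 and 605.3 CPM, CACNA2D1 127.8 and 297.2 CPM). The cholesterol synthesis list had a median of 0.50, with 11 of 23 genes higher, 12 within 1.5-fold and 0 lower; INSIG1, a sensor of sterol levels, was 2.51-fold and the squalene synthase FDFT1 2.42-fold higher. The p53 target list had a median of 0.34 (6 of 23 higher, 0 lower), with DDB2 2.92-fold and the cell cycle inhibitor CDKN1A 1.93-fold higher. The hypoxia and glycolysis median was 0.30 (3 of 25 higher, 1 lower), with LDHA 2.60-fold and the glucose transporter SLC2A3 2.40-fold higher but SLC2A1 at 190.0 and 119.7 CPM. These medians lay at or below percentile 0.490 or at or above percentile 99.8 of 10000 random lists matched on size and expression.

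Within GABAergic neuron-like cells (11319 WT and 750 SPG4), the lists of mitochondrially encoded transcripts and of genes induced by activity or dissociation had the highest medians. Mitochondrially encoded transcripts had a median log2 ratio of 0.94 (0.92 to 0.95), with 11 of 12 higher and 0 lower. MT-ND5 stood at 197.7 and 481.9 CPM and MT-CYB at 401.4 and 807.1 CPM. The median mitochondrial share of UMIs per cell differed between the clusters of this class, from 0.052% in cluster 15 to 0.686% in cluster 1. Dissociation and immediate early genes had a median of 0.69 (0.64 to 0.75), with 8 of 16 higher and 1 lower. JUNB stood at 52.1 CPM in WT and 227.8 CPM in SPG4, FOSB at 16.8 and 75.5 CPM and NR4A1 at 21.8 and 96.2 CPM, while the heat shock gene HSPA1A, which shares reads with HSPA1B and is uncertain, stood at 14.3 and 1.82 CPM. The immediate early median was 0.01 with each library clustered on its own and 1.38 at a minimum of 50 CPM. ARC, an immediate early gene of synapses, was among the 4 highest genes of this class at 7.65-fold (6.93 to 8.43), with the collagen COL24A1 at 11.4-fold (10.5 to 12.5), the phosphodiesterase PDE1A at 8.66-fold and the cadherin CDH18 at 7.86-fold. PDE1A and CDH18 stood at 1107 and 1805 CPM in SPG4 glutamatergic neuron-like cells, against 86.2 and 228.5 CPM here. The 4 lowest were PEG3, at 65.3 CPM in WT and 0 UMIs in SPG4 (at least 300-fold lower), the transcription factors EBF1, 132-fold lower (60.7 to 361), and FOXP2, 13.2-fold lower (10.8 to 16.3), and the zinc finger gene ZNF439, 5.61-fold lower. Clusters 8 and 3 held 34.1% and 25.9% of the SPG4 cells of this class but 8.63% and 15.5% of the WT cells. Clusters 1 and 2 held 18.0% and 17.9% of the WT cells but 14.1% and 7.87% of the SPG4 cells. COL24A1 was among the 10 leading genes of cluster 8. EBF1 led cluster 15, which held 7.62% of the WT and 3.07% of the SPG4 cells. The ratios of these 2 genes therefore mix cluster shares with levels inside clusters.

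Some other lists in GABAergic neuron-like cells depended on how clusters entered the class. Synapse genes had a median of 0.52 (13 of 32 higher, 1 lower), with the kinase CAMK2A 3.06-fold, PCLO 2.17-fold, HOMER1 2.17-fold and SYN2 2.12-fold higher in SPG4, and ion channels a median of 0.30 (7 of 19 higher, 0 lower), with CACNA1E 2.63-fold higher. Forebrain patterning factors had a median of -0.52 (6 of 13 lower, 1 higher), with SIX3 at 19.2 and 0.436 CPM, NR2F2 at 66.3 and 21.4 CPM, and NR2F1 at 28.2 and 12.6 CPM. When the WT clusters were weighted as in SPG4, an alternative chosen after the data were seen, these medians became 0.11, -0.06 and 0.01, while mitochondrially encoded transcripts stood at 1.05, immediate early genes at 0.52 and SPAST at a log2 ratio of -0.37. Cholesterol synthesis genes had a median of 0.43 (4 of 19 higher, 0 lower; STARD4 2.66-fold, INSIG1 2.25-fold) and stood at 0.40 with those weights. The p53 target list (0.31, 3 of 18 higher, 0 lower; DDB2 2.02-fold, CDKN1A 1.89-fold) and the unfolded protein response (0.25, 2 of 18 higher, 1 lower; the stress factor ATF3 7.35 and 13.7 CPM) became -0.16 and -0.37 with each library clustered on its own. Nuclear genes of oxidative phosphorylation had a median of 0.25, with 45 of 46 within 1.5-fold and cytochrome c, CYCS, 2.09-fold higher.

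Within cycling progenitor-like cells (762 WT and 410 SPG4), the 4 highest genes in SPG4 included markers of intermediate progenitors and glutamatergic neurons, and the 4 lowest included GABAergic markers. The medians of the WNT and BMP signalling and extracellular matrix lists were higher. EOMES stood at 0.313 CPM in WT and 123.1 CPM in SPG4, 393-fold higher (180 to 1073), against 262.6 CPM in SPG4 intermediate progenitor-like cells. MIR924HG was 428-fold (250 to 805) and TMEM132D 197-fold (112 to 382) higher. NEUROD6 had 0 UMIs in WT and 82.0 CPM in SPG4, at least 523-fold higher against 3 UMIs, while SPG4 glutamatergic neuron-like cells held 1073 CPM and SPG4 barcodes under 1000 UMIs 879.1 CPM. The 4 lowest were the connexin GJA1, 15.2-fold (11.6 to 20.3), DLX6-AS1, 12.8-fold (11.9 to 13.8), GAD2, 12.5-fold lower (11.4 to 13.8), and the calcium-binding protein CALB2, at 244.9 and 19.1 CPM. WNT and BMP signalling genes had a median of 0.78 (0.69 to 0.84), with 5 of 10 higher and 1 lower: LEF1 stood at 0.627 and 75.8 CPM, DKK3 at 14.2 and 48.4 CPM and ID4 at 90.1 and 226.9 CPM, but WNT7A at 21.5 and 7.30 CPM. That median was 0.40 with no minimum CPM. Extracellular matrix genes had a median of 0.62 (0.54 to 0.73), with 9 of 14 higher and 1 lower; the basement membrane collagens COL4A1 and COL4A2 were 9.44-fold and 9.58-fold and the laminin LAMC1 3.05-fold higher, while the fibrillar collagen COL1A2 stood at 191.6 and 20.7 CPM. Cluster 21 held 65.0% of the WT cells and cluster 20 held 93.4% of the SPG4 cells of this class.

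Other lists in cycling progenitor-like cells had smaller medians in either direction. The integrated stress response had a median of 0.46 (6 of 15 higher, 0 lower; ATF5 3.74-fold, STC2 3.08-fold), cholesterol synthesis 0.44 (3 of 21 higher, 0 lower; STARD4 2.54-fold, HMGCS1 1.89-fold), the unfolded protein response 0.38 (5 of 19 higher, 1 lower; DDIT3 3.04-fold, HERPUD1 1.97-fold) and hypoxia and glycolysis 0.36 (7 of 21 higher, 0 lower; PFKFB4 2.26-fold, SLC2A3 2.15-fold). Axon growth genes had a median of 0.37 (9 of 24 higher, 5 lower), with the semaphorin receptors NRP1 and NRP2 4.16-fold and 5.83-fold higher. Synapse genes had a median of 0.34 (7 of 24 higher, 2 lower; PCLO 17.0 and 77.9 CPM, NRXN3 4710 and 805.5 CPM), which became -0.11 with called doublets kept and -0.01 with genes centred within each library. Mitochondrially encoded transcripts had a median of -0.38, with 3 of 13 lower and 0 higher, and nuclear genes of oxidative phosphorylation one of -0.24, with 0 of 46 beyond 1.5-fold.

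**Figure D3:**
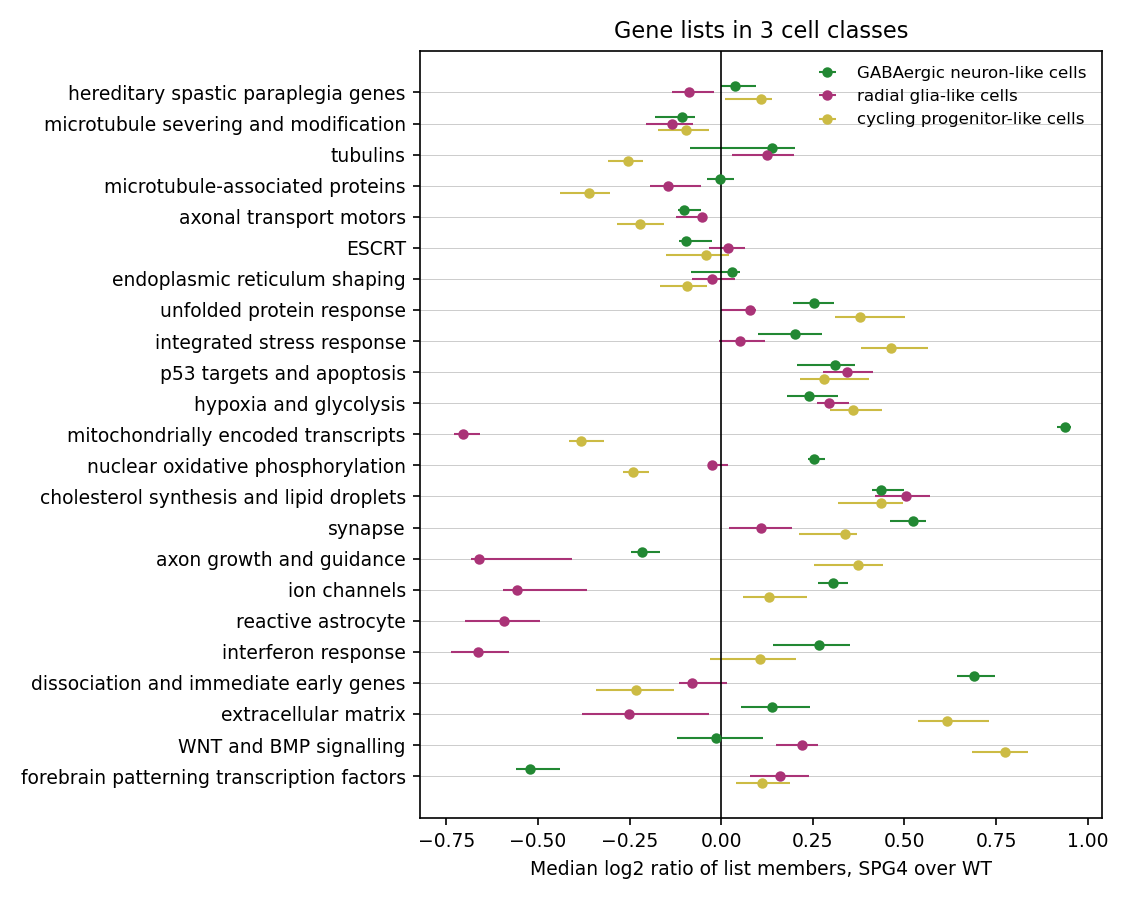
Median log2 ratio of SPG4 over WT (horizontal axis) of the measured members of 23 gene lists (vertical axis) in 3 cell classes, with 1 point per class where at least 5 members were measured and bars for the 95% counting interval. Mitochondrially encoded transcripts lie at 0.94 in GABAergic neuron-like cells and at -0.70 in radial glia-like cells.

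Several lists were tied to the function of spastin. Other hereditary spastic paraplegia genes had medians of 0.04, -0.09 and 0.11 in GABAergic, radial glia-like and cycling cells, with 29 of 31, 28 of 32 and 25 of 30 members within 1.5-fold. Genes of microtubule severing and modification had medians of -0.11, -0.13 and -0.10, and the deglutamylase AGBL4 stood at 17.3 and 9.59 CPM, 17.4 and 3.95 CPM, and 32.0 and 5.04 CPM. Tubulins had medians of 0.14, 0.12 and -0.25, microtubule-associated proteins 0.00, -0.14 and -0.36, and axonal transport motors -0.10, -0.05 and -0.22. In cycling progenitor-like cells, 11 of 28 microtubule-associated genes were lower and 1 higher, and their median lay below all 10000 random lists. The median of axonal transport motors there (5 of 27 lower, 0 higher) lay below the central 95% of random lists, -0.15 to 0.19. So did microtubule-associated genes in radial glia-like cells (5 of 29 lower, 2 higher) at percentile 1.56, and the severing (1 of 18 lower, 0 higher) and ESCRT lists in GABAergic neuron-like cells at percentiles 2.23 and 2.39. In cycling progenitor-like cells doublecortin, DCX, stood at 1595 and 424.4 CPM, STMN2 at 552.9 and 141.9 CPM, and the neuronal tubulin TUBB3 at 1029 and 330.0 CPM. These are genes of neurons, GABAergic markers were lower in the same class (GAD2 612.5 and 48.9 CPM), and cluster 21 held 65.0% of its WT but 6.59% of its SPG4 cells, so lower microtubule genes were not separated from fewer neuronal transcripts. In GABAergic neuron-like cells TUBB3 stood at 1242 and 794.6 CPM and STMN2 at 1646 and 912.3 CPM. ESCRT genes, whose complex recruits spastin, had medians of -0.10, 0.02 and -0.04 with 0 members beyond 1.5-fold in any of the 3 classes. Genes that shape the endoplasmic reticulum had medians of 0.03, -0.03 and -0.09, with 2 members beyond 1.5-fold in radial glia-like cells, RTN1 (446.7 and 181.6 CPM) and ARL6IP1 (327.3 and 196.4 CPM), and 0 in the other classes. Tubulin genes share sequence, and single members are uncertain where reads could be split.

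The position of genes along the chromosomes was also examined, after the data were seen, since some members of the lists above share a region. From COP1 to ZNF692 on the long arm of chromosome 1 (175944831 to 248859144 of GRCh38), the 231 measured genes had median log2 ratios of 0.58, 0.60 and 0.60 in GABAergic, radial glia-like and cycling cells, against 0.02, 0.05 and 0.02 for the 669 genes of the rest of the chromosome. PHLDA3, of the p53 target list, and BTG2, of the immediate early list, lie in this region, and the immediate early median of GABAergic neuron-like cells was 0.52 without the region's genes. Other genes named above were not marked by position. The folds of any that lie in this region include its difference between the libraries. Around PEG3 on chromosome 19, 4 of 24 measured genes within 1 Mb (ZNF542P, ZNF667, ZNF667-AS1 and ZNF471) were also at least 10-fold lower in SPG4 in all 3 classes, and 20 were not. These zinc finger genes share sequence, and their single values are uncertain.

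**Figure D4:**
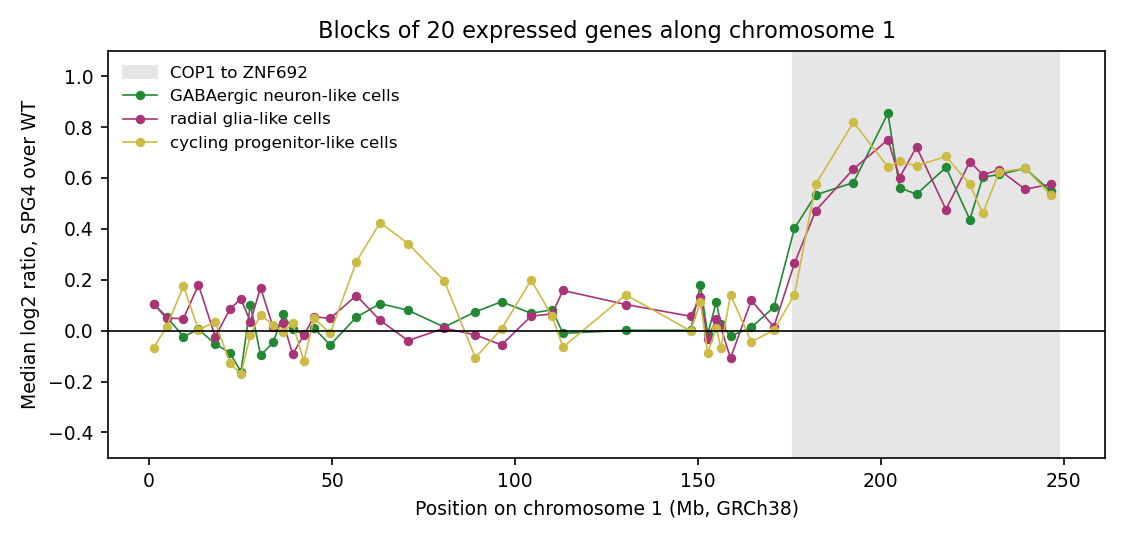
Median log2 ratio of SPG4 over WT (vertical axis) in 45 blocks of up to 20 neighbouring expressed genes against the position of the block on chromosome 1 in Mb of GRCh38 (horizontal axis), with 1 line per cell class and shading from COP1 to ZNF692. The 12 blocks centred in the shaded part lie between 0.14 and 0.85, and the 33 blocks before it between -0.17 and 0.42.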

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

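The tests of depth and of differences other than genotype were chosen only after the result was seen, and the test of the cell filter was written before it.

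The glutamatergic neuron-like cells of the SPG4 library had no counterpart in WT, and 2 technical explanations were weighed. The cell filter and doublet removal did not take such cells out of WT, since 5 glutamatergic markers together stood at 5.9 CPM in the WT barcodes left out and at 1499.4 CPM in the SPG4 barcodes left out, a ratio of 0.00394 (0.00345 to 0.00448). Depth per cell does not account for it either, since with each cell thinned to 3000 UMIs 0 WT cells held 2 or more of these markers (upper bound of the exact interval 0.0248%), while 56.7% of SPG4 cells held 2 or more of them and fewer than 2 GABAergic markers. With 1 library per genotype, the genotype and a difference between the differentiations, the libraries or the labels cannot be told apart. Cortical and ventral identity may vary between organoid differentiations of 1 line, which a second differentiation of each genotype would address.

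A signal also appeared in barcodes that failed the filter and so entered no cell class. The same 5 markers stood at 12 CPM in WT, from 19 UMIs in 2338 barcodes, and at 1427.6 CPM in SPG4, from 4968 UMIs in 6227 barcodes.

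Some gene groups went in opposite directions in different classes. Mitochondrially encoded transcripts had a median log2 ratio of 0.94 in GABAergic neuron-like cells and -0.70 in radial glia-like cells. Ion channels had medians of 0.30 in GABAergic neuron-like cells and -0.56 in radial glia-like cells, and axon growth genes of 0.37 in cycling progenitor-like cells and -0.66 in radial glia-like cells. The ion channel median of GABAergic neuron-like cells changed sign with WT clusters weighted as in SPG4, an alternative chosen after the data were seen. Its opposite direction therefore depended on the weight of clusters. These differences between classes were not tested.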

How the results depend on the processing

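Of the values below, those with WT clusters weighted as in SPG4, without clusters of low UMI counts and without genes of distal chromosome 1q come from tests chosen only after the results were seen. No paired analysis was possible because each genotype has 1 library. Every result here rests on that single pair, and the class sums behind the counting intervals ranged from 9319261 UMIs (SPG4 cycling) to 150104018 UMIs (WT GABAergic). Among 46 alternatives for SPAST, 9 moved the log2 ratio beyond its counting interval and 0 reversed a ratio whose interval excluded 1. Of 124 alternatives for shares of cells 74 moved the share, and of 576 for named genes 268 moved the ratio and 0 reversed it. The named genes were picked for their extreme ratios, so a reversal was unlikely beforehand. Of 796 for the 56 reported list medians, 238 moved the median and 7 reversed it, where a reversal was counted only for a median outside the central 95% of random lists with an interval that excluded 0, a requirement set after the values were seen. Without the comparison with random lists, and over all 113 list medians, 62 of 1550 alternatives reversed the sign, in 33 of those medians. The minimum CPM decides much of which genes are named: of the 12 highest genes of radial glia-like cells, 3 were also named with no minimum and 6 at 100 CPM. No setting shifted the median of all genes by over 0.1. The GABAergic class gave no values with genes centred within each library, since SPG4 then held under 200 such cells. For each value below, the cause was not tested. A test of whether the SPAST difference follows from cell classes, written before, was dropped after the class ratios were seen, and a test of free RNA was dropped before it was run; the values are in the report.

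Cell filter and doublets. The WT share of GABAergic neuron-like cells, 69.9%, was 58.4% with the looser filter, 70.8% with the stricter filter and 64.2% with called doublets kept, and the SPG4 share of glutamatergic neuron-like cells, 53.2%, was 49.3%, 65.8% and 54.8%. With the looser filter the mitochondrial median was 0.72 in GABAergic and -0.83 in radial glia-like cells, interferon in radial glia-like cells -0.79, SPAST in cycling cells -0.74 and WNT and BMP in cycling cells 0.68. With the stricter filter the mitochondrial median of radial glia-like cells was -0.76. With doublets kept, mitochondrial medians were 0.87 (GABAergic) and -0.81 (radial glia-like), and in cycling cells extracellular matrix was 0.77, WNT and BMP 0.86, and synapse reversed from 0.34 to -0.11.

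Clustering. At resolution 0.5 the shares were 64.8% and 58.6%, the mitochondrial median of GABAergic cells 0.87 and WNT and BMP 0.61. At resolution 2 the shares were 67.6% and 54.5%, the SPG4 GABAergic share 5.50%, the mitochondrial median of radial glia-like cells -0.73 and WNT and BMP 0.88. With each library clustered on its own, the shares were 68.2% and 58.8% and the SPG4 GABAergic share 6.63%. In GABAergic cells SPAST was then -0.38, mitochondrial transcripts 1.09 and immediate early genes 0.01, and the unfolded protein response and p53 targets reversed to -0.37 and -0.16; the mitochondrial median of radial glia-like cells was -0.77 and WNT and BMP 0.66. With genes centred within each library the shares were 62.3% and 63.3%, the SPG4 GABAergic share 0.278% and the WT glutamatergic share 1.25%; the mitochondrial median of radial glia-like cells was -0.85, SPAST in cycling cells -0.36, and synapse in cycling cells reversed to -0.01.

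Cell cycle. The WT and SPG4 shares of 12.3% and 10.3% were 20.7% and 20.03% at a minimum of 2 UMIs, 8.09% and 5.47% at 5 UMIs, 9.41% and 7.31% thinned to 2000 UMIs, and 42.5% and 59.4% without thinning.

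Normalization, weights and depth. With the mean of per-cell CPM, SPAST was -0.49 over all cells, -0.38 in GABAergic and 0.12 in radial glia-like cells; in GABAergic cells mitochondrial transcripts were 0.75 and immediate early genes 0.58, in radial glia-like cells mitochondrial transcripts -0.57 and interferon -0.48, and in cycling cells extracellular matrix 0.76 and WNT and BMP 0.91. With cells thinned to 3000 UMIs, SPAST over all cells was -0.45, mitochondrial medians 0.73 (GABAergic) and -0.53 (radial glia-like), immediate early genes 0.57, interferon -0.45 and WNT and BMP 0.86. With median-of-ratios scaling, mitochondrial medians were 0.91 (GABAergic) and -0.73 (radial glia-like). With WT clusters weighted as in SPG4, GABAergic cells gave SPAST -0.37, mitochondrial transcripts 1.05, immediate early genes 0.52, ion channels reversed to -0.06 and patterning factors reversed to 0.01. Without clusters of low UMI counts, radial glia-like cells gave SPAST -0.15 and interferon -0.56.

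Minimum CPM, pseudocount and region. With no minimum, immediate early genes in GABAergic cells were 0.52, interferon in radial glia-like cells -0.31, WNT and BMP 0.40, and the reactive astrocyte median over all cells reversed from -0.54 to 0.01. At a minimum of 50 CPM they were 1.38, -0.58 and 1.02 for the first 3. With a pseudocount of 5 CPM interferon was -0.57. Without genes of distal chromosome 1q, immediate early genes were 0.52.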

Other observations

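The tests of cell classes and of a few genes for chromosome 1q, and of cell classes for PEG3, were chosen only after the result was seen, as were the region and PEG3 themselves; the other tests were written before their result.

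Of 31 measured autophagy and lysosome genes, 7 were at least 1.5-fold lower in SPG4 radial glia-like cells, 23 lay within 1.5-fold and 1, WIPI1, was higher, with a median log2 ratio of -0.24 at percentile 0.05 of random lists. The lysosomal membrane protein LAMP1 stood at 122.6 CPM in WT and 70.3 CPM in SPG4, the sphingolipid activator precursor PSAP at 487.7 and 279.3 CPM, and the protease CTSA at 19.3 and 9.12 CPM. The same list lay at 0.09 in GABAergic neuron-like and 0.04 in cycling progenitor-like cells. COX6C, of oxidative phosphorylation, stood at 200.3 and 134.6 CPM in cycling progenitor-like cells. The NOTCH list as a whole did not stand out in cycling progenitor-like cells, with a median of 0.22 at percentile 88.0 of random lists. Of its 10 measured genes there, 2 were higher, 1 was lower and 7 lay within 1.5-fold. Its target HES1 stood at 11.6 and 80.2 CPM in that class. In GABAergic neuron-like cells, 10 of 29 axon growth genes were lower and 2 higher (median -0.21), with CNTN1 at 172.4 and 390.2 CPM, and LDHA, of glycolysis, stood at 55.4 and 127.6 CPM.

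Genes of distal chromosome 1q, from COP1 to ZNF692, were higher in SPG4 in the 3 classes in which the region was searched for, so their medians there (lowest 0.58) and shares of genes above 0 (lowest 90.9%) were partly set by the search. In cells not used to find it, the medians were 0.62 in oligodendrocyte precursor-like cells and 0.53 in cluster 16, above the highest of equally long runs elsewhere (0.15 and 0.02), with 84.4% and 91.3% of genes above 0. These values leave neither the cell classes nor a few genes as the cause, and they fit an extra copy of the region in the SPG4 cells. MDM4, an inhibitor of p53 chosen after its values were seen, was 1.55-fold, 1.80-fold and 1.79-fold higher in GABAergic, radial glia-like and cycling cells. Single genes of the region varied, with log2 ratio quartiles of 0.38 and 0.79 in GABAergic neuron-like cells. RNPEP was 2.87-fold, 3.68-fold and 3.34-fold higher in the 3 classes, and TIMM17A 2.93-fold, 3.03-fold and 2.79-fold, which is more than the region's medians. Gains of 1q recur in cultured human pluripotent stem cells, so a copy gain in culture may be a candidate explanation, but DNA was not analysed here, and any gain cannot be separated from the SPAST edit with 1 library per genotype.

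PEG3, at chromosome 19, 56810077 to 56840728 of GRCh38, was near 0 in SPG4. The cell classes do not account for it, since it was at least 79.8-fold lower in each of the 3 classes when SPG4 is set to 3 UMIs. Loss of the whole region within 1 Mb does not either, since the lowest of 3 class medians of its genes was -0.28. A smaller loss at PEG3 was not excluded, since a few lost genes would hardly move that median. ZIM2, of the same imprinted cluster, was also lower, at 13.1 and 0.799 CPM in GABAergic neuron-like cells. A loss as large as that of PEG3 at many imprinted genes does not account for it. Of 19 other measured imprinted genes, 0 were at least 10-fold lower in all 3 classes. NNAT, one of the 19 and named after its values were seen, was lower by less, at 825.6 and 255.9 CPM in GABAergic, 743.2 and 85.4 CPM in radial glia-like and 1062 and 154.8 CPM in cycling cells. Silencing at PEG3 and the neighbouring zinc finger genes may be a candidate explanation and was not tested, as methylation was not analysed here.

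Of 9094 genes measured in all 3 classes, 14 were at least 4-fold lower in SPG4 in each and 4 were at least 4-fold higher in each: NEUROD6, NEUROD2, TTR and NR4A2. Each of the 4 had a higher level over all SPG4 cells than in any of the 3 classes, so RNA from other cells was not excluded as a source. NR4A2, a nuclear receptor, stood at 101.8 CPM over all SPG4 cells and at 46.0, 15.3 and 17.4 CPM in GABAergic, radial glia-like and cycling cells. The 14 lower genes included PEG3 but were not confined to its region. Among them were SNTG2 on chromosome 2, ZNF717 on chromosome 3, CCDC152 on chromosome 5 and PUS7L on chromosome 12.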
